A study of Homo sapiens with 1346 samples.

How the data were processed

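The series measured RNA of single cells from retinal organoids derived from H1 human embryonic stem cells at 8 months. Per the labels' protocols, a suspension of live cells or nuclei was dispensed on a nanowell chip, wells with a single live cell or nucleus were chosen by microscopy, and 3′ end libraries were made and sequenced on an Illumina HiSeq2500. The deposited unit is read counts per gene: 1 HTSeq count table per well, deposited by the authors, with 23228 gene symbols each. Per the submitters' processing notes, CASAVA, TopHat2, HTSeq and DESeq2 1.10.1 were used, with hg19 and GRCh37 named as the genome build. Whether molecular identifiers were collapsed is not given in the sources used here, so the counts are treated as reads. Gene coordinates were not used here.

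All 1346 tables held whole-number counts, and 0 pairs of tables were identical. The totals of the HTSeq categories that name no gene were kept out of all sums: 29.4% of all reads were in no feature, 14.5% were not uniquely aligned and 1.49% were ambiguous, and 54.7% (55935779 reads) were assigned to genes. R and C in the sample titles were read as row and column of a chip of 72 by 72 wells, which splits the wells into rows 0 to 35 and 36 to 71. These are technical parts of 1 chip and not replicates. The number of cultures, organoids or chips is not given in the sources used here, so the series was treated as 1 sample, and no test across cells was made.

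The filters, clustering settings, comparisons, cell type markers, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Cells with at least 500 detected genes and genes found in at least 5 of these cells were kept. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes, without ribosomal protein and mitochondrial genes, gave 20 principal components, 15 neighbours and Leiden clusters at resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, fixed seed). Class shares come from this clustering. Scrublet called 1 doublet, which was kept in the main results, and leaving it out or leaving out the 5% of wells with most counts were alternatives.

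A cluster took a class name from fixed markers only. The scoring rule was set and revised after the clusters had been seen. It compares each marker's CPM in the cluster with the median of the other clusters, with 10 CPM added to both. A name needs at least 3 measured markers, at least 3 of them 2-fold higher and found in at least 5% of the cells, at least as many 2-fold higher as not, and at least 1 among the 10 leading genes found in at least 20% of the cells. A cluster stayed unnamed where another class had more markers among the 10 leading genes or where another of the cone, rod, Müller glia and bipolar classes scored at least 0.5 times as high. Where the best-scoring class was horizontal or amacrine and the markers of both met the 2-fold conditions, the name held both, and only the better-scoring one needed a leading marker. Under an earlier rule, against all other cells, the shallow cone-like cluster of 172 cells was unnamed and the cone-like share was 22.6% in place of 35.7%. The rule left clusters of 142 cells (10.8%) and 40 cells (3.04%) unnamed.

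For the comparisons between classes, genes were split at random into 2 sets of 11614. Cells were clustered on the 1000 most variable genes of each set and the clusters named by the same rule, and each gene was measured between the classes of the clustering that did not use it. The naming markers came from both sets, so the direction of marker genes is not independent of the names. Of the cone-like cells, 78.9% and 70.0% kept their class in the 2 clusterings, of the rod-like cells 70.2% and 85.1% and of the Müller glia-like cells 80.6% and 94.5%. Counts were summed per class and given as CPM (counts per 1000000) with exact Poisson 95% intervals. Log2 ratios were taken with 10 CPM added to both classes, which understates the change of low genes, and fold differences, with the counts of list genes at least 2-fold apart, are ratios of the CPM itself. TMM factors from edgeR 4.0.16 (R 4.3.3) were an alternative only.

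Gene lists, fixed before the data were examined, covered cone, rod and shared phototransduction, photoreceptor transcription factors, outer segment and connecting cilium, ribbon synapse, visual cycle and retinoid handling, glycolysis and lactate, oxidative phosphorylation, glial homeostasis, gliosis and glial stress, the Notch pathway, cone and cone-rod dystrophy genes, retinitis pigmentosa genes, thyroid hormone and retinoic acid handling, immediate early and heat shock genes, and nuclear noncoding RNAs. A member counted as measured with at least 10 CPM in one of the 2 classes. PKM and KIZ were found in the tables under the older symbols PKM2 and PLK1S1, through the synonyms of a table of the GRCh38.p14 assembly used for names only. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of this sample.

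The rule for named genes took up to 4 measured members of each list with the largest absolute log2 ratio, and outside lists and markers the 10 genes furthest in each direction among those with at least 100 CPM and detection in at least 20% of cells of the higher class and the same direction in both parts of the chip. Cone opsin genes, NRL, ARR3, CRX and RLBP1 were always named. An item withheld for evaluation is not reported here. Other genes in the text are list members or markers named as examples after their values were seen.

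Shares of cells with a read carry exact Clopper-Pearson 95% intervals, and a count of 0 is given the limit of 3 counts. For detection at equal depth each cell was thinned to 11675 reads, the 20th percentile of the kept cells, which leaves out 264 cells. The share in Müller glia-like cells serves as the background of opsin detection. OPN1LW and OPN1MW were summed.

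The measurement between classes was tested on simulated counts with 200 changed genes. For cone-like against rod-like cells (8841 genes), 4-fold, 2-fold, 0.5-fold and 0.25-fold changes were recovered at median log2 ratios of 1.84, 0.92, −0.88 and −1.80, with 50 of 50 in the right direction at each size. For photoreceptor-like against Müller glia-like cells (8871 genes) they were 1.82, 0.92, −0.90 and −1.81, also 50 of 50 each. In the simulation 99.4% to 99.8% of cells fell in the right class, and depth did not differ between classes. The test therefore does not cover misplaced cells or classes of unequal depth, and the naming of clusters was not part of it. Alternatives covered cell filters, doublets, resolution, neighbours, principal components, parts of the chip, classes from all genes, mean per-cell CPM, TMM factors, a pseudocount of 1 CPM, no filter on low counts, thinning and detection at 3 reads. A minimum of 10000 reads, totals without MALAT1 and classes clustered without opsin genes were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9 were used.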

Results

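Retinal organoids grown from the human embryonic stem cell line H1 were profiled at 8 months, and 1346 wells of a nanowell chip were sequenced singly with a 3′ end protocol. All cells belong to 1 group and no culture, animal or chip replicate is named in the labels, so the whole series is 1 sample. Reads assigned to genes ranged from 250 to 235053 per well, with a median of 28878.5, and the median number of detected genes was 2183. Of the wells, 1317 had at least 500 detected genes and were kept, with a median of 30259 reads in genes, and the 29 left out had a median of 2596. MALAT1, a nuclear noncoding RNA, took 6.73% of all gene counts. The intervals given with the values cover counting error only, since reads without stated collapsing of molecular identifiers are not independent molecules and cells of 1 sample are not replicates. No p-value is given for that reason.

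The first question, set by a series title that calls the organoids cone-enriched, was which cells the organoids held. Cone-like cells were the largest class, 470 of 1317 cells or 35.7% (95% Clopper-Pearson interval 33.1% to 38.3%). Rod-like cells made up 21.4% (19.2% to 23.7%, 282 cells) and Müller glia-like cells, the main glia of the retina, 19.2% (17.1% to 21.4%, 253 cells). Inner retinal neurons were fewer, with 92 bipolar-like cells (6.99%, 5.67% to 8.50%) and a cluster of 38 cells with raised horizontal and amacrine cell markers (2.89%, 2.05% to 3.94%), of which only the horizontal markers ONECUT1 and ONECUT2 were among its leading genes. The other 182 cells (13.8%, 12% to 15.8%) stayed unnamed. Of these, 142 formed a shallow cluster with Müller glia markers above their level in rod-like cells.

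The cone-like class joined a deep cluster of 298 cells with a median of 57173 reads, led by ARR3, GUCA1C and MYL4, and a shallow cluster of 172 cells with a median of 11064.5 reads, led by RAB41, GUCA1C and ARR3. The deep cluster alone was 22.6% of cells, close to the rod-like share. ARR3 stood at 10036 CPM (counts per 1000000) in the deep and 5209 CPM in the shallow cluster, against 818 CPM in rod-like cells. Leading genes of the rod-like cluster included CCKBR, SAG, GNAT1 and PDE6G. The Müller glia-like class also joined a pair of clusters, of 135 and 118 cells, both with RLBP1, CRYM, PRSS35 and SPP1 among their leading genes. Its larger cluster was also led by CCL2 and IFIT3, a chemokine gene and an interferon-induced gene. The cone transcript ARR3 differed between the 2, at 466 CPM in the larger and 2958 CPM in the smaller. Bipolar-like cells were led by CXCL14, ISL1 and LRTM1, and the horizontal or amacrine-like cells by STMN2, HMP19 and CACNG3.

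Median reads in genes per cell were 41710.5 in cone-like, 21030.5 in rod-like and 43868 in Müller glia-like cells. Thinned to 11675 reads each, the median cell had 2203.5 detected genes among cone-like, 1643.5 among rod-like and 2167.5 among Müller glia-like cells, with 90, 64 and 13 shallower cells left out. The thinned medians keep rod-like cells lowest of the 3. Shares depended on the cell filter and the clustering: with at least 10000 reads per cell, a filter chosen after the data were seen, Müller glia-like cells were 34.6%, and the bipolar-like share ran from 0% to 7.83% and that of horizontal or amacrine-like cells from 0% to 7.86% over the settings tried. The cone-like share ran from 25.1% to 36.6%. All these settings used the final naming rule, and under the earlier rule the cone-like share was 22.6%.

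**Figure D1:**
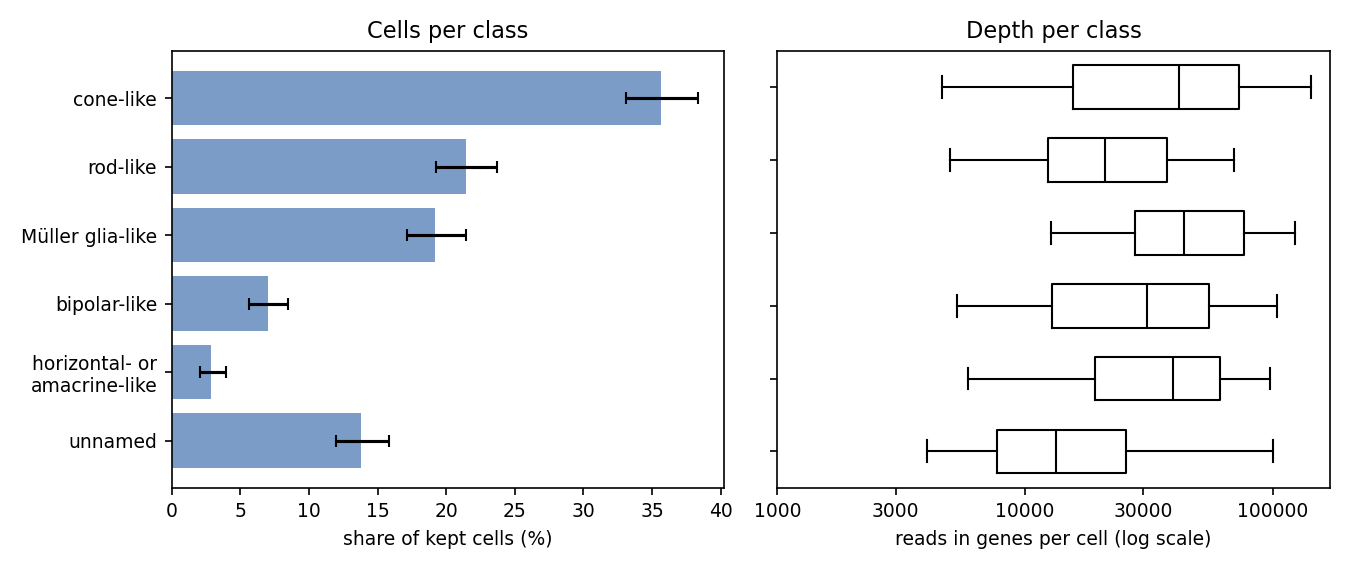
The left panel plots the share of the 1317 kept cells in each class, with bars from 0 and exact 95% intervals, and the right panel plots reads in genes per cell on a log axis, with boxes at the quartiles, lines at the medians and whiskers from the 5th to the 95th percentile. Cone-like cells have the tallest bar, at 35.7%, and rod-like cells a lower median, 21030.5 reads, than cone-like cells, 41710.5 reads.

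The second question was how the transcripts of cone-like and rod-like cells differed. Cone-like cells had far more of the cone versions of the light response machinery. PDE6C, the catalytic subunit of the cone phosphodiesterase, stood at 220 CPM (214 to 226) in cone-like against 9.71 CPM (7.61 to 12.2) in rod-like cells, a 22.6-fold difference. CNGB3, a subunit of the cone cyclic nucleotide-gated channel, differed 16.9-fold and ARR3, cone arrestin, 10.5-fold (9931 CPM, 9890 to 9972, against 942 CPM, 920 to 964). Rod-like cells in turn had 11.2 times the transcript of PDE6A, a catalytic subunit of the rod phosphodiesterase, 788 CPM (768 to 809) against 70.1 CPM (66.7 to 73.7). The sums ran over 409 or 352 cone-like and 222 or 269 rod-like cells of the 1 sample, depending on which set of genes the classes were taken from.

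Of the 12 measured cone phototransduction genes, 10 were at least 2-fold higher in cone-like cells and 0 lower, with a median log2 ratio of 2.54, above every one of 10000 random lists matched on expression. Among them GNAT2, the cone transducin subunit, stood at 1125 against 126 CPM, GUCA1C at 3711 against 384 CPM and PDE6H at 11258 against 2002 CPM. All 11 measured rod phototransduction genes were at least 2-fold lower in cone-like cells, with a median log2 ratio of −2.81, below every random list. Rod arrestin SAG stood at 532 CPM in cone-like and 5258 CPM in rod-like cells, and the channel subunit CNGA1 at 18.7 and 243 CPM. Classes were named from markers that include 9 members of each of these lists, so their direction is not independent evidence. The 3 other measured cone genes had a median of 2.24 and the 2 other rod genes −2.65. Of 11 measured phototransduction genes shared by rods and cones, 9 lay within 2-fold and the median was 0.06 (percentile 47.4), while the calcium-sensing cyclase activators GUCA1A (6919 against 1300 CPM) and GUCA1B (3399 against 1088 CPM) were higher in cone-like cells.

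Photoreceptor transcription factors split by type. NR2E3 and NRL, which set rod fate, stood at 73.3 and 36.7 CPM in cone-like and at 696 and 263 CPM in rod-like cells, and SAMD11 and ESRRB were also lower in cone-like cells. The thyroid hormone receptor gene THRB (230 against 86.3 CPM), the retinoid X receptor gene RXRG (102 against 41.5 CPM) and MEF2C were at least 2-fold higher in cone-like cells. CRX, the factor common to both types, was nearly level at 391 and 357 CPM, while OTX2, also common to both, was lower in cone-like cells at 283 against 570 CPM. Over the 16 measured factors, 3 were higher and 5 lower by at least 2-fold, and the median log2 ratio was −0.43 (percentile 0.17). Of the 16, 6 are naming markers, and the 10 others had a median of −0.47. NR2E3, NRL, THRB and RXRG are among the naming markers, so their direction is not independent evidence.

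Genes of the outer segment and connecting cilium were mostly level, with 18 of 21 within 2-fold and a median of −0.14 (percentile 3.72). The exceptions were TULP1, at 393 CPM in cone-like and 196 CPM in rod-like cells, ROM1, a disc rim protein gene, at 768 and 4537 CPM, and CNGB1 at 788 and 1606 CPM. Of 19 measured ribbon synapse genes, 17 lay within 2-fold, with a median of −0.07 (percentile 25.4), among them CABP4 (log2 0.91), PCLO (0.81) and DMD (−0.77), while the low genes BSN (3.34-fold) and RIMS1 were higher in rod-like cells. The visual cycle and retinoid list had a median of −0.44 (percentile 0.57), with 7 of 14 genes within 2-fold. RLBP1, RGR and CRABP1 were at least 2-fold lower in cone-like cells, and 4 genes at least 2-fold higher: STRA6, CRABP2, RBP4, a retinol carrier gene, at 96.5 against 11.4 CPM, and DHRS3, a retinal reductase gene, at 79.8 against 12.9 CPM.

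Nuclear-encoded oxidative phosphorylation genes ran higher in cone-like cells as a group, with a median log2 ratio of 0.63 over 36 measured genes, above every random list. Most of these differences were small, and 34 of 36 stayed within 2-fold. UQCRH stood at 1306 against 488 CPM and NDUFV2 at 891 against 365 CPM, followed by NDUFA4 (log2 0.97) and ATP5G1 (0.92). The classes differed in depth. In one set of genes the cone-like clusters had medians of 56992 and 21284 reads and the rod-like cluster 23514.5. In the other set the medians were 52672.5 and 21577 reads. A part for depth in this shift was not tested, and no value is given for the shallow cone-like cluster alone. Glycolysis and lactate genes showed no such shift, with a median of 0.14 (percentile 82.2) and all 22 within 2-fold, among them PKM2 (log2 0.73), HK2 (0.72) and PFKP (−0.68).

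Gliosis and glial stress genes were lower in cone-like than in rod-like cells, 7 of 12 by at least 2-fold and 0 higher, with a median of −1.09, below every random list. GFAP, an intermediate filament gene, stood at 42.8 against 141 CPM and NES at 35.6 against 112 CPM. Of 14 measured Müller glia markers, 13 were lower in cone-like cells, though only 3 by at least 2-fold, with RLBP1 at 65.4 against 134 CPM and SLC1A3 at 66.4 against 129 CPM. The other, the carbonic anhydrase gene CA2, was higher at 810 against 225 CPM, and AQP4 was also higher, 34.6 against 31.4 CPM, in the classes clustered on all genes. In that clustering most of these markers were low in the deep cone-like cluster only. VIM, also on the gliosis list, stood at 257 CPM in the deep and 637 CPM in the shallow cluster, against 528 CPM in rod-like cells. For TF the values were 771, 2635 and 2062 CPM, and for CLU 144, 418 and 333 CPM. In the shallow cluster only RLBP1, SLC1A3, SOX2 and HES1 were lower than in rod-like cells. The glial homeostasis list as a whole had a median of −0.10 (percentile 25.3, 11 of 13 within 2-fold). Notch pathway genes had a median of −0.37 (percentile 15.4, 7 measured), with the ligand gene DLL1 at 21.5 against 2.13 CPM and HES6 at 26.4 against 6.52 CPM on one side and the receptor gene NOTCH2 at 11 against 35.2 CPM on the other.

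Of 34 measured retinitis pigmentosa genes, 13 were at least 2-fold lower in cone-like cells and 3 higher (RP9, TULP1 and DHDDS), with a median of −0.38, below every random list, and 12 of the 34 are also naming markers. Of 27 measured cone and cone-rod dystrophy genes, 6 were higher (among them PDE6C, CNGB3 and GNAT2) and 2 lower, PITPNM3 and RIMS1, with a median of 0.01 (percentile 50.6). Thyroid hormone and retinoic acid genes had a median of −0.04 (percentile 50.7, 6 measured), with CRYM lower at 123 against 262 CPM. For the same 6 genes the median was 0.54 in chip rows 0 to 35 and −0.48 in rows 36 to 71, so it has no settled direction. With measured genes chosen within each part of the chip, the medians were 0.523 and −0.755. Immediate early and heat shock genes lay at −0.14 (percentile 15.0, 11 of 16 within 2-fold), with DUSP1 (27.1 against 111 CPM), FOSB and IER3 lower and HSPA1A and HSPA1B higher by at least 2-fold. Nuclear noncoding RNAs lay at −0.20 (percentile 21.7, 4 measured), with MALAT1 at 44495 against 63868 CPM.

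Outside the lists and markers, the largest differences toward cone-like cells among well-detected genes were those of RAB41 (19.1-fold, 117 against 6.12 CPM), HRASLS (8.77-fold), MAP6 (8.63-fold), TDRG1 (8.07-fold) and MYL4 (7.36-fold). They were followed by PEX5L, PCP4, XRCC4, SIX6 and MATN2, at 4.52- to 5.84-fold. Toward rod-like cells they were those of CCKBR, a cholecystokinin and gastrin receptor gene (12.1-fold, 561 against 46.2 CPM), DDC (10.4-fold), GABRR3 (9.75-fold), CLUL1 (9.48-fold) and PPAP2C (8.78-fold). STC1, UNC13C, SNTB2, AANAT and RASSF2 followed at 5.06- to 7.98-fold. DDC and AANAT encode enzymes of monoamine and melatonin synthesis. These 20 were taken from genes with the same direction in both parts of the chip. The median log2 ratio of all 9030 measured genes was −0.05. Median reads per cell in cone-like cells were 1.98 times those in rod-like cells, although the shallow cone-like cluster lay below rod-like cells (11064.5 against 21030.5 reads).

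The third question was what set photoreceptor-like cells, cones and rods together, apart from Müller glia-like cells. Photoreceptor-like cells had 11.9 times the GNAT2 transcript, 902 CPM (892 to 913) against 76.1 CPM (71.2 to 81.3), and 17 times that of CNGB3. Müller glia-like cells had 14.4 times the RLBP1 transcript, which encodes a retinaldehyde-binding protein of the visual cycle, at 1162 CPM (1142 to 1181) against 80.6 CPM (77.4 to 83.8). They also had 11.3 times SLC1A3, a glutamate transporter gene, 17.2 times SPP1, osteopontin, and 6.91 times GLUL, glutamine synthetase. All of these genes but SPP1 are naming markers, so their direction is not independent evidence. The sums ran over 631 or 621 photoreceptor-like and 236 or 255 Müller glia-like cells of the 1 sample. Cone-like cells gave most of the photoreceptor-like counts, 23553033 or 22315855, against 6741543 or 7518909 from rod-like cells. Values of photoreceptor-like cells are therefore mostly those of cone-like cells.

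All 12 measured cone phototransduction genes were at least 2-fold higher in photoreceptor-like cells, with a median log2 ratio of 2.00, above every random list, and 2.89 when cells with at least 100 detected genes were kept. Rod phototransduction genes had a smaller median of 0.92 (percentile 99.9), and CNGB1, PDE6G and CNGA1 of 11 reached 2-fold. This median joins rod-like cells with the cone-like cells that gave most counts. In the classes clustered on all genes, SAG stood at 5306 CPM in rod-like, 597 in cone-like and 916 in Müller glia-like cells. For GNAT1 the values were 3904, 488 and 622 CPM. Of 11 shared phototransduction genes 10 were higher, with a median of 1.63, led by PDC, GUCA1A and GUCA1B. Transcription factors had a median of 0.88 with 9 of 16 higher, among them RAX2, CRX, NEUROD1 and SAMD7, CRX at 384 against 117 CPM. Outer segment and cilium genes had a median of 1.41 with 15 of 21 higher, such as TULP1, RPGRIP1 and IMPG1, and ribbon synapse genes 1.18 with 12 of 18 higher, such as CABP4, SNAP25 and STX3. The medians of the shared, transcription factor, outer segment and synapse lists all lay above every random list, and TBX2 and RIMS1 were the members of these 4 lists lower by at least 2-fold. No ribbon synapse gene is a naming marker, while the other lists hold 6 to 9 of them.

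Photoreceptor transcripts were also read in Müller glia-like cells. ARR3 was detected in 96.5% of them at 1556 CPM, against 7666 CPM in photoreceptor-like cells, and PDE6H stood at 2191 against 8926 CPM. Rod-like cells alone stood at 942 CPM for ARR3 and 2002 CPM for PDE6H, both below Müller glia-like cells. The rod factor NRL stood at 49.7 CPM in Müller glia-like and 93.7 CPM in photoreceptor-like cells, and at 263 CPM in rod-like cells alone. In the classes clustered on all genes, ARR3 was read in 86.8% to 97.7% of the cells of every class. The Müller glia-like values came mainly from the smaller cluster of 118 cells. PDE6H stood at 4004 CPM there against 669 CPM in the larger, SAG at 1580 against 267 CPM and NRL at 84.0 against 26.5 CPM. The source of these reads was not tested.

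Glial genes went the other way. Of 14 measured glial homeostasis genes, 8 were at least 2-fold lower in photoreceptor-like cells and 1 higher, with a median of −1.21, below every random list. Of the 14, 4 are naming markers, and the 10 others had a median of −0.91. CA14 stood at 21.7 against 280 CPM in Müller glia-like cells and GPX3, a secreted glutathione peroxidase gene, at 238 against 2064 CPM. Of 13 gliosis and stress genes, 7 were lower and 0 higher, with a median of −1.09, also below every random list, led by SPP1 (355 against 6107 CPM), IFITM3, CRYAB and VIM (337 against 2435 CPM). VIM is a naming marker, and the 12 other gliosis and stress genes had a median of −0.94. GFAP, the usual gliosis gene, was nearly level at a log2 ratio of −0.06. Notch pathway genes had a median of −0.55 (percentile 2.51), 4 of 9 lower and 2 higher, DLL1 and DLL3, with HES1 at 56.6 against 619 CPM and NOTCH1 at 2.41 against 34.6 CPM.

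Retinoid genes divided between the cell types. The visual cycle list had a median of −0.22 (percentile 6.91) with 7 of 15 lower and 4 higher: RLBP1, RGR and RDH10 belonged to the Müller glia-like side, with RDH10 at 248 against 32.6 CPM, and RBP4, ABCA4, RDH12 and RBP3 to the photoreceptor side. Thyroid hormone and retinoic acid genes were mostly lower in photoreceptor-like cells, 6 of 9 with 2 higher, at a median of −1.04 (percentile 0.04) that became −0.332 with no filter on low counts. CRYM, which binds thyroid hormone, stood at 158 against 2461 CPM and CYP26A1, which breaks down retinoic acid, at 7.88 against 151 CPM, while RXRG was higher at 86.5 against 26.7 CPM.

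Energy genes split within glycolysis. ENO1 was 3.28-fold and the glucose transporter gene SLC2A1 2.59-fold higher in Müller glia-like cells, while ENO2, the neuronal enolase gene, was 3.31-fold and ALDOC 2.40-fold higher in photoreceptor-like cells. The list's median was 0.19 (percentile 59.9), with 5 of 22 higher and 2 lower. Oxidative phosphorylation genes were higher in photoreceptor-like cells, 8 of 36 by at least 2-fold and 0 lower. The median was 0.71 (percentile 99.99), and the list was led by ATP5G1 (2.75-fold) and ATP5A1 (2.62-fold). Rod-like cells alone stood at 581 CPM for ATP5G1 against 361 CPM in Müller glia-like cells, but at 488 against 479 CPM for UQCRH. In the immediate early and heat shock list, 8 of 16 genes were at least 2-fold lower in photoreceptor-like cells and 0 higher, at a median of −0.83 below every random list. The 8 were immediate early genes and not heat shock genes: ATF3 stood at 51.5 against 377 CPM and FOS at 440 against 2120 CPM. Nuclear noncoding RNAs had a median of −0.35 (percentile 8.13, 4 measured), with NEAT1 4.87-fold and MALAT1 1.71-fold higher in Müller glia-like cells.

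Both disease gene lists were higher in photoreceptor-like cells. Of 27 cone and cone-rod dystrophy genes, 22 were at least 2-fold higher and 1 lower, RIMS1 (median 1.43), and of 34 retinitis pigmentosa genes 13 were higher and 0 lower (median 0.80), both above every random list. Of the 27 and 34 genes, 10 and 12 are naming markers, and the others had medians of 1.12 and 0.59. IMPDH1 and PRCD, which are not naming markers, were 3.19- and 3.22-fold higher. Outside the lists and markers, MYL4 (11.8-fold), MATN2 (10.2-fold), C6orf191, CC2D2A, ECHDC2, TDRG1, GUK1, MPP4, ARMC9 and LBH were the furthest toward photoreceptor-like cells, the last at 4.52-fold. TDRG1 was not higher in rod-like cells alone, at 24.3 against 28.3 CPM in Müller glia-like cells. The furthest toward Müller glia-like cells were PRSS35 (15.3-fold, 1220 against 79.7 CPM), F3, LIX1, PRSS23, S100A16, CCL2, IFIT3, ADAMTS1, IFITM2 and IFITM1, 10.4- to 18.4-fold. IFITM1, IFITM2 and IFIT3 are interferon-induced genes, and CCL2 and IFIT3 were read in 33.9% and 33.3% of Müller glia-like cells. The median log2 ratio of all 9431 measured genes was 0.04.

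**Figure D2:**
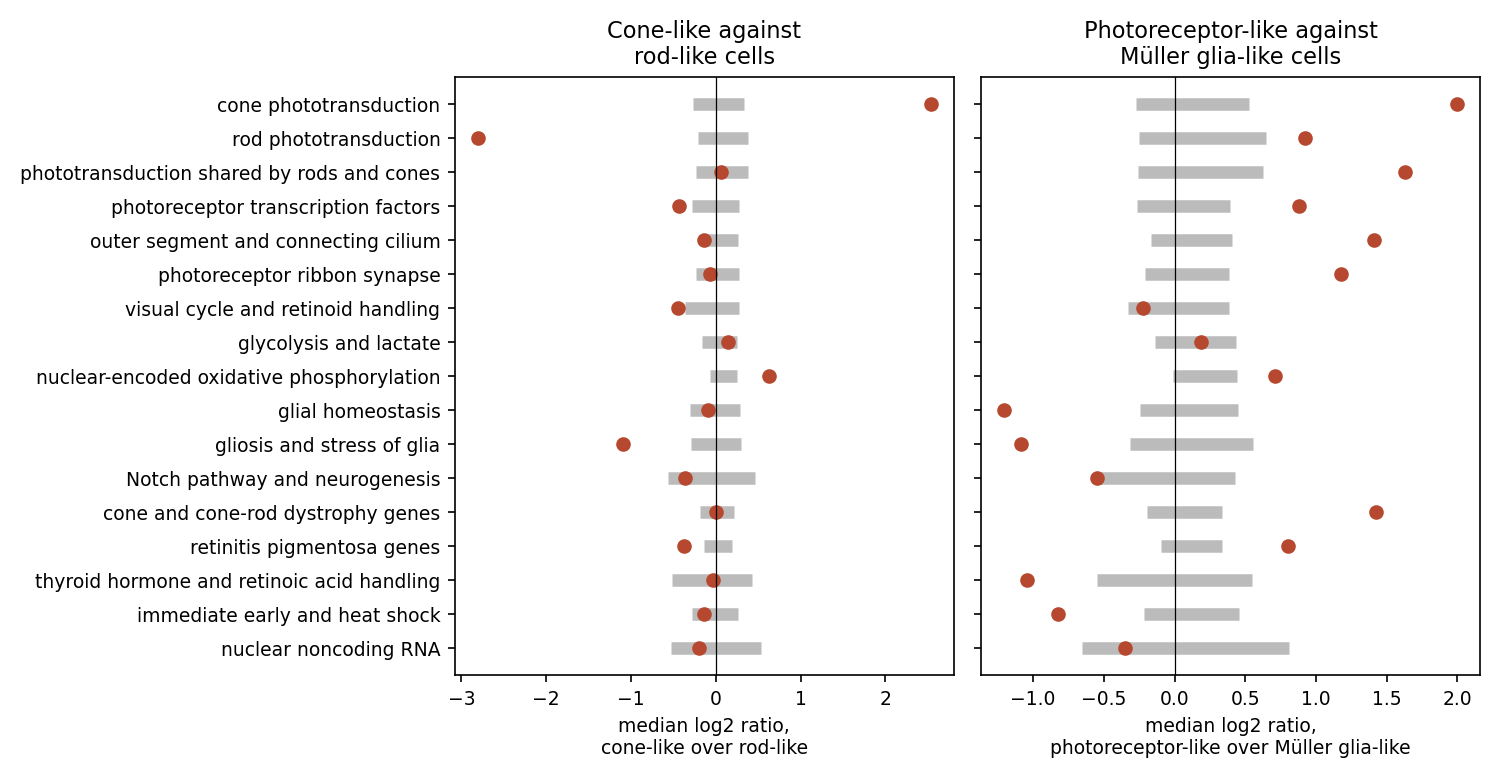
Each point is the median log2 ratio of the measured genes of 1 fixed list, for cone-like against rod-like cells and for photoreceptor-like against Müller glia-like cells, and grey bars span the central 95% of 10000 random lists matched on expression. Cone and rod phototransduction lie at 2.54 and −2.81 in the first comparison, and glial homeostasis at −1.21 in the second.

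The last question was which cone opsins the cone-like cells used. Red and green opsin transcripts, OPN1LW or OPN1MW, were read in 74 of 470 cone-like cells, 15.7% (12.6% to 19.4%), against 1.98% (0.645% to 4.55%) of Müller glia-like and 1.77% (0.578% to 4.09%) of rod-like cells. Nearly all came from OPN1LW, with 108 reads in 92 cells against 6 reads in 4 cells for OPN1MW, and OPN1MW2 had 0 reads. These near-identical genes can lose reads that align to both, so the split between them is uncertain and the shares of cells may be too low. Cone-like cells held 88 reads of these genes, at most 3 in 1 cell. With at least 3 reads required, 1 of 470 cone-like (0.213%), 1 of 282 rod-like (0.355%) and 0 of 253 Müller glia-like cells remained. The difference between classes was therefore not seen at that minimum. Blue opsin, OPN1SW, was read in 1.70% (0.738% to 3.33%) of cone-like cells, inside the interval of the 1.58% (0.432% to 4.00%) of Müller glia-like cells. By that share blue cones were not told apart from background. One cone-like well held 40 of the class's 68 OPN1SW reads, in 14425 counts, against at most 11 in a rod-like and 7 in a Müller glia-like well, but it ranked 435 of 470 in 6 summed cone genes (6239 CPM against a class median of 32064 CPM). In 0 of 470 cone-like cells were both kinds of cone opsin read. With OPN1SW read in so few cells, independent detection would give 1.26 such cells, so the 0 does not limit how many cells express both.

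Thinned to 11675 reads, OPN1LW or OPN1MW was read in 13 of 380 cone-like cells, 3.42% (1.83% to 5.78%), and in 0 of 240 Müller glia-like and 0 of 218 rod-like cells, which allow up to 1.25% and 1.38%. It was also read in 2 of 76 bipolar-like cells, 2.63% (0.320% to 9.18%), and 2 of 106 unnamed cells, 1.89% (0.229% to 6.65%), intervals that overlap that of cone-like cells. Unthinned, the shares were 5.43% and 3.30%. Thinned cells all had the same depth, while the unthinned medians were 41710.5 reads in cone-like and 43868 in Müller glia-like cells. Of the 513 OPN1SW reads in the sample, 380 came from 1 well of the horizontal or amacrine-like class, which held 2 wells with OPN1SW in all.

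**Figure D3:**
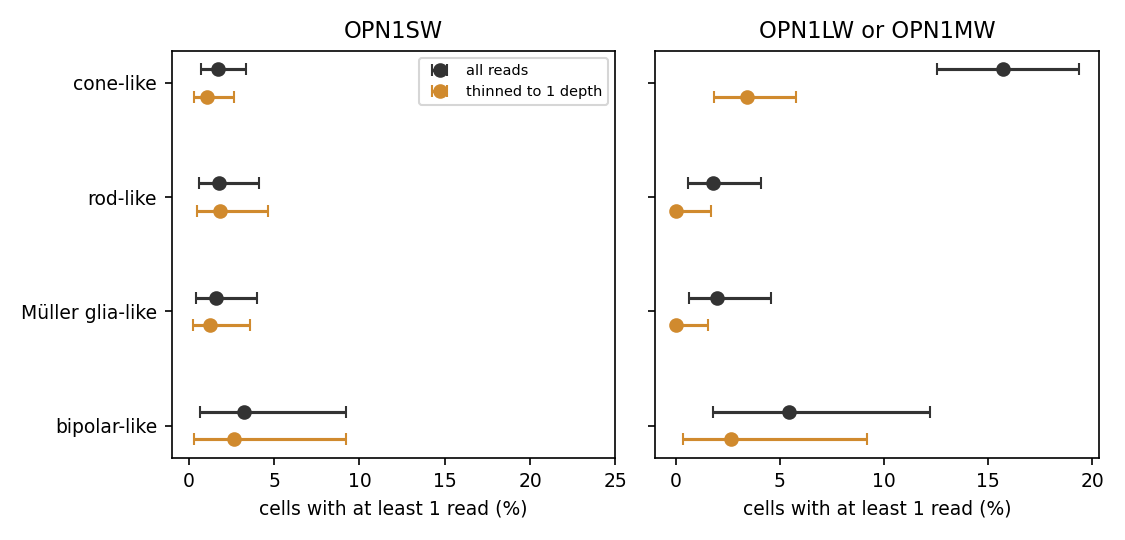
Points are the percent of cells with at least 1 read of OPN1SW and of OPN1LW or OPN1MW in 4 classes, black for all reads and orange after thinning to 11675 reads, with exact 95% intervals. Red and green opsin is read in 15.7% of cone-like cells and in 1.98% of Müller glia-like cells.

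Of 85 markers of cell types beyond photoreceptors, bipolar cells and Müller glia checked over all kept cells, 47 were read in under 1% of cells. All 7 immune markers and all 4 pluripotency markers fell under 1%, and the ganglion cell factor POU4F2 and the melanin genes TYR and MLANA had 0 reads, which allows up to 0.228% of cells with a read and does not limit the cells that express them at a lower level. The division genes MKI67 and TOP2A were read in 1.14% (0.639% to 1.87%) and 1.82% (1.17% to 2.70%) of cells. The markers read in more than 20% of cells were SERPINF1 (44.3%), SFRP2 (40.1%), GFAP (36.8%), CCND1 (34.5%), TTR (30.6%), KDR (28.5%) and RGR (22.6%). Among bipolar-like cells, ISL1 stood at 868 CPM, CA10 at 343, TMEM215 at 208, the metabotropic glutamate receptor gene GRM6 at 123 and its channel TRPM1 at 68.7 CPM. ARR3 stood at 4377 CPM in the same cells, above its 1699 CPM in Müller glia-like cells. In the horizontal or amacrine-like cells ONECUT2 stood at 681 CPM, GAD1 at 243, ONECUT1 at 173, PROX1 at 138 and TFAP2A at 124 CPM.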

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

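The settings with at least 10000 reads, with MALAT1 left out of the totals and with classes clustered without opsin genes were chosen after seeing the data. No list median or named gene's log2 ratio of at least 1 in size changed sign. Smaller ones did: 21 values of 6 list medians (main size up to 0.366) and 14 values of 6 named-gene ratios (up to 0.678). Among them was the thyroid hormone and retinoic acid median of cone-like against rod-like cells, 0.523 in chip rows 0 to 35. Turned into folds, 575 of 578 list medians changed by no more than 1.5 times, which leaves room for a change of sign near 0, as did 2680 of 2839 ratios of named genes. Of 66 shares of cells 43 stayed inside the counting interval, of 35 opsin shares 27, and of 170 shares of single markers of other cell types 128. Opsin detection was limited by depth, and reads that align to both OPN1LW and OPN1MW may lower it further. No paired analysis was possible because there is 1 group and replicate names are well positions. For the values below the cause was not tested, except that thinning and the 3-read minimum lower detection by construction.

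With at least 1000 detected genes the shares were 31% cone-like, 28.8% rod-like, 23.3% Müller glia-like, 7.86% horizontal or amacrine-like and 3.27% unnamed. With at least 100 detected genes they were 27.2% cone-like, 0% bipolar-like, 0% horizontal or amacrine-like and 34% unnamed, and the cone phototransduction median of photoreceptor-like against Müller glia-like cells was 2.89. Without the top 5% of wells Müller glia-like cells were 14.2% and unnamed cells 19.3%, and with at least 10000 reads 34.6% and 2.91%. At resolution 0.5 cone-like cells were 28.8%, bipolar-like 2.88% and unnamed 25.1%, and at resolution 2.0 cone-like cells were 25.1% and unnamed 25.7%. With 30 neighbours cone-like cells were 29.1% and unnamed 20.8%, and with 10 principal components cone-like cells were 28.5%, bipolar-like 4.56% and unnamed 23%. The thyroid hormone and retinoic acid median was −0.332 with no low-count filter for photoreceptor-like against Müller glia-like cells, and −0.755 in chip rows 36 to 71 for cone-like against rod-like cells. OPN1LW or OPN1MW was read in 3.42% of cone-like and 0% of rod-like cells after thinning, in 0.213% and 0.355% with at least 3 reads, and in 19.7% of cone-like cells with at least 1000 detected genes.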

Other observations

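The tests of carried-over OPN1SW reads and of shallow sequencing were chosen only after their results were seen. A cluster of 40 cells that stayed unnamed (3.04% of cells, median 57444 reads) was led by G0S2, HOPX, LGALS1, CCL2 and FBLN2, and GFAP and FN1 were among its leading genes. GFAP stood at 1844 CPM there, against 88.5 and 54 CPM in the Müller glia-like clusters, and was read in 25 of the 40 cells. AQP4, a glial water channel gene, stood at 925 CPM and S100B, an astrocyte marker, at 238 CPM, while RLBP1 stood at 96.3 CPM, below both Müller glia-like clusters. Division genes were also highest there, with UBE2C at 232 CPM and CDK1 at 113 CPM, though MKI67 was read in only 2 and TOP2A in 3 of its cells.

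Some genes listed as markers of 1 cell type were most abundant in another. CABP5, a calcium-binding protein gene listed for bipolar cells, stood at 1759 CPM in rod-like and 351 CPM in bipolar-like cells. SFRP2, a secreted Wnt antagonist listed for progenitors, stood at 942 CPM in the larger Müller glia-like cluster and 96.9 CPM in rod-like cells. Transferrin, TF, was the most abundant Müller glia marker, at 14623 CPM in Müller glia-like and 1022 CPM in cone-like cells.

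In the horizontal or amacrine-like class 1 well held 380 of 381 OPN1SW reads. No other well in the files held more than 40 OPN1SW reads (a ratio of 9.50). These counts argue against carry-over from such a well, but the test was chosen once they were known. Wells without a file, free RNA taken up by this well and amplification of few molecules were not tested. A second cell, a cone, in the same well could not be decided by the correlation of OPN1SW with 6 cone genes across the class (Spearman rho 0.209). That well ranked 1 of 38 in these cone genes, at 21155 CPM against a median of 2315 CPM in its class, so a shared well stays open. The design gives no biological explanation to test.

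A shallow unnamed cluster of 142 cells (median 11223 reads), led by NOTCH2, COL18A1 and NEAT1, gave 15.5% of its counts to MALAT1. Its MALAT1 CPM was 2.04 times that of the shallow cone-like cluster (75785 CPM, median 11064.5 reads), but the latter was itself 1.73 times the deep cone-like cluster (43888 CPM), and the cells were noted for their MALAT1, so a part for shallow sequencing stays open. Loss of cytoplasmic RNA, from nuclei or leaking cells, goes with the share of uniquely placed reads outside genes, 49.1% or 1.32 times the highest named class. Ribosomal protein genes were at 0.947 times the lowest, but this difference was small. Their share was 3.61%, against 3.81% in cone-like cells and 3.79% in the shallow cone-like cluster. Over all 182 unnamed cells, with the cluster of 40 cells at 5.75%, it was 4.82%, above every named class. The labels speak of cells or nuclei without marking wells. No biological explanation was tested.

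Cone-like cells had 1.98 times the median reads of rod-like cells (21030.5), although the class joins clusters with medians of 57173 reads (298 cells) and 11064.5 reads (172 cells), the latter below rod-like cells. Position on the chip is argued against, since the ratio was 1.91 in one part of the chip and 2.05 in the other. Cell size and the amount of RNA per cell stay open, and no biological explanation was tested.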
